A study of Homo sapiens with 5 samples.

How the data were processed

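The series holds 5 arrays of 3 RNA samples from CHP-134 cells, with 2 technical arrays of MYCN-A3 sample 1, 1 array of MYCN-A3 sample 2 and 2 technical arrays of the DMSO sample, and groups were taken from the labels' source names and titles. Per the labels' protocols, exposure lasted 6 h, to MYCN-A3 at 10 nM or to DMSO at 0.15%, and total RNA was extracted with a column kit. The series design states that 150 ng per sample was labelled with a spike-in kit.

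Per the file headers, the scanner files were made with Agilent Feature Extraction 11.0.1.1 from 1-colour (Cy3) scans, and their processed signal is a spot intensity after background subtraction and detrending, not normalized between arrays. The median signal and local background columns are raw intensities per the file headers. The deposited series values are on a log2 scale. Set against the scanner columns, each deposited array rose with the background-subtracted median signal (rank correlation 1 on every array). Over bright spots, a straight line fitted on the linear scale had a slope of 0.958 to 1.07 per array. Whether the relation is linear for dim spots was not tested. The medians of the deposited arrays were 5.41, 5.41, 5.39, 5.39 and 5.41, so the authors' values appear scaled on the median, without gene centring and with the same direction as the scanner signal. Limma is named for the expression analysis per the submitters' processing notes, and which of its background and scaling steps the authors ran is not given in the sources used here.

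Each array held 62976 spots, of which 58717 were not controls, for 50599 distinct probes. Spots marked by the scanner software as non-uniform or population outliers were left out, and spots of 1 probe were averaged on the log2 scale. Values were log2 of the processed signal minus the array's log2 75th percentile over non-control spots. Probes were kept where they were well above background, by the scanner's own call, on every array of at least 1 group. This left 17114 genes and transcripts, each represented by its brightest kept probe. Of 1780 called genes with several kept probes, 191 had a probe that moved the other way in both treated samples, and for 44 of those it did so at least 2-fold. A 75th percentile over all probes moves with the share of probes detected, which was lower on the treated arrays, so other scalings were compared throughout.

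The files used hold accessions and no gene names. Accessions were matched without version to the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), and 29033 of 30919 RefSeq-style accessions matched, giving 20992 symbols. The other 21566 probes, among them 8183 with Ensembl transcript accessions, kept their accession, and 3816 of the tested features are such transcripts. The array headers name an older genome build, so no coordinates are given. Gene length is the span in the same RefSeq table, which had a value for all 13298 tested genes with a symbol, 77.7% of all tested features, so the length results hold for genes with a symbol.

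The arrays of 1 RNA sample were averaged, and limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided) compared 2 MYCN-A3 samples with 1 DMSO sample, with 1 residual degree of freedom and a prior of 4.06 degrees of freedom. Benjamini-Hochberg adjustment ran over all genes and transcripts tested. The 21 gene lists, 891 names of which 885 matched a symbol, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The lists cover the MYCN locus, MYC targets, neuronal differentiation, p53 targets, DNA repair, apoptosis, G1/S, G2/M, histones, stress responses, heat shock, immediate early genes, adrenergic and mesenchymal states, interferon, NF-kB, NRF2 and AHR, cholesterol, ribosomal proteins, oxidative phosphorylation and hypoxia. The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

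The rule named all measured genes of the MYCN locus list, the 12 genes with the largest rise and the 12 with the largest fall among those past an adjusted p of 0.05 with the same sign in both treated samples, leaving out provisional and clone names, and up to 4 called members of each list with the largest change. A few genes that the rule names are not reported here. The 2 sets of 12 were ranked only over genes well above background on all 5 arrays, a limit that the rule as fixed beforehand did not hold. Where all probes of a gene were not well above background on every array of a group, the change is a bound, the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

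The arrays lay on 2 slides, each scanned once and each holding both groups, so slide was tested as a block over 5 arrays and within each slide. Other alternatives were normexp background correction with an offset of 50, run on the median signal because the files used hold no mean signal, quantile normalization, scaling by the array median or by 6 spike-in probes, no filter on dim probes or a filter on all arrays, the mean over probes, the RNA sample as a random block, 5 independent arrays, an intensity trend or robust moderation, the deposited values, and leaving out arrays or samples. Chosen after seeing the data were the 75th percentile over detected probes, centring on the median tested gene, the single slides, and the length relation over subsets of genes.

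The scripts were tested on simulated data drawn for the comparison of MYCN-A3 with DMSO over 17114 genes. With 200 genes changed, 8.2% of those changed by 1 log2 unit, 78.9% by 2 and 96.8% by 4 were recovered, with 9 false calls. With 49.4% of the genes changed, 80.4%, 99.2% and 99.9% were recovered and 3.17% of the calls were false. The simulation gave all 3 samples the same spread, drew genes independently and added no shift between arrays. These rates therefore test the scripts and do not give the share of false calls in the measured data. Preparation and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.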

Results

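Gene expression was measured in CHP-134 cells, an established human neuroblastoma line, after 6 h with 10 nM MYCN-A3 or with 0.15% DMSO, the solvent control. MYCN-A3 is an alkylating pyrrole-imidazole polyamide, a synthetic DNA minor groove binder that carries a reactive alkylating group, and the series title gives the amplified MYCN gene as its intended target. Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays. Of the 5 arrays, 2 held RNA of MYCN-A3 sample 1, 1 held RNA of MYCN-A3 sample 2 and 2 held RNA of the single DMSO sample. The arrays of 1 RNA were averaged, so the comparison set 2 treated samples against 1 control sample. The labels do not say whether the RNA samples came from separate cultures, so the p-values measure only the spread between the 2 treated samples, which may be technical, and the lone DMSO sample was assumed to vary as they did.

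The treated arrays were dimmer. The 75th percentile of the signal was 163.7, 202.9 and 184.6 intensity units on the MYCN-A3 arrays against 376.6 and 360.4 on the DMSO arrays. Between 38.7% and 42.4% of the probes were well above background on the MYCN-A3 arrays, against 43.9% and 43.1% on the DMSO arrays. The 6 spike-in probes, which report RNA added in the same amount to each labelling reaction, had mean log2 signals of 11.19, 11.46 and 10.50 on the MYCN-A3 arrays against 11.04 and 10.65 on the DMSO arrays. No spot was saturated. With 3 RNA samples, their number limits the precision.

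The comparison of MYCN-A3 with DMSO asks which transcripts change within 6 h of exposure. Long genes fell relative to short genes. The median genes of the length classes above 100 kb changed by -0.90 to -0.998 log2 units relative to the median of all tested genes. Of the mitosis, histone and adrenergic neuroblastoma identity genes measured, 19 of 48, 21 of 50 and 14 of 30 fell. As lists each stood below the other genes with a preset correlation but not with an estimated one (adjusted p = 0.964 with an estimated correlation for each). With 1 residual degree of freedom the test with an estimated correlation can hardly call any list. Of 40 targets of the p53 tumour suppressor 16 rose and 7 fell, and as a list they did not stand apart (adjusted p = 0.73). Among them GDF15, PLK2 and BBC3 changed by 3.49, 3.38 and 2.89 log2 units relative to the median gene, and KITLG fell. HEXIM1 rose by 3.77. HEXIM1 encodes an inhibitor of the elongation kinase P-TEFb. MYCN itself, the named target, had no direction that held under every scaling of the arrays.

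Of 17114 genes and transcripts tested, 6430 were higher and 2901 lower with MYCN-A3 at an adjusted p of 0.05 (limma, Benjamini-Hochberg), and 3179 rose and 2118 fell at least 2-fold in both treated samples. The 2 arrays of the DMSO RNA differed at least 2-fold at 184 of them, the 2 arrays of MYCN-A3 sample 1 at 389, and the 2 treated samples at 455. The median absolute log2 difference was 0.83 between the treatments and 0.20 between the treated samples. The 0.83 includes the shift of the median tested gene by 0.48 that came with this scaling. The split between higher and lower depended on how the arrays were scaled. With the arrays scaled to their 75th percentile, the median tested gene shifted by 0.48 log2 units, and 68.9% of the calls were higher. The 2-fold counts, 3179 up and 2118 down, became 501 and 4208 with spike-in scaling, 336 and 3520 in the deposited values, 920 and 3634 with the array median, 1166 and 3194 centred on the median gene, 1713 and 2721 with quantile normalization, 1631 and 2742 with the 75th percentile over probes detected on all arrays, and 1423 and 1238 with normexp. For the calls, quantile normalization gave 3214 higher and 3423 lower, scaling by the array median 1347 and 4756, spike-in scaling 240 and 2203, the deposited values 912 and 6308, and centring on the median gene 1946 and 4017. The 75th percentile over probes detected on all arrays gave 3361 higher and 3467 lower, and normexp background correction 8559 and 2908.

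**Figure D1:**
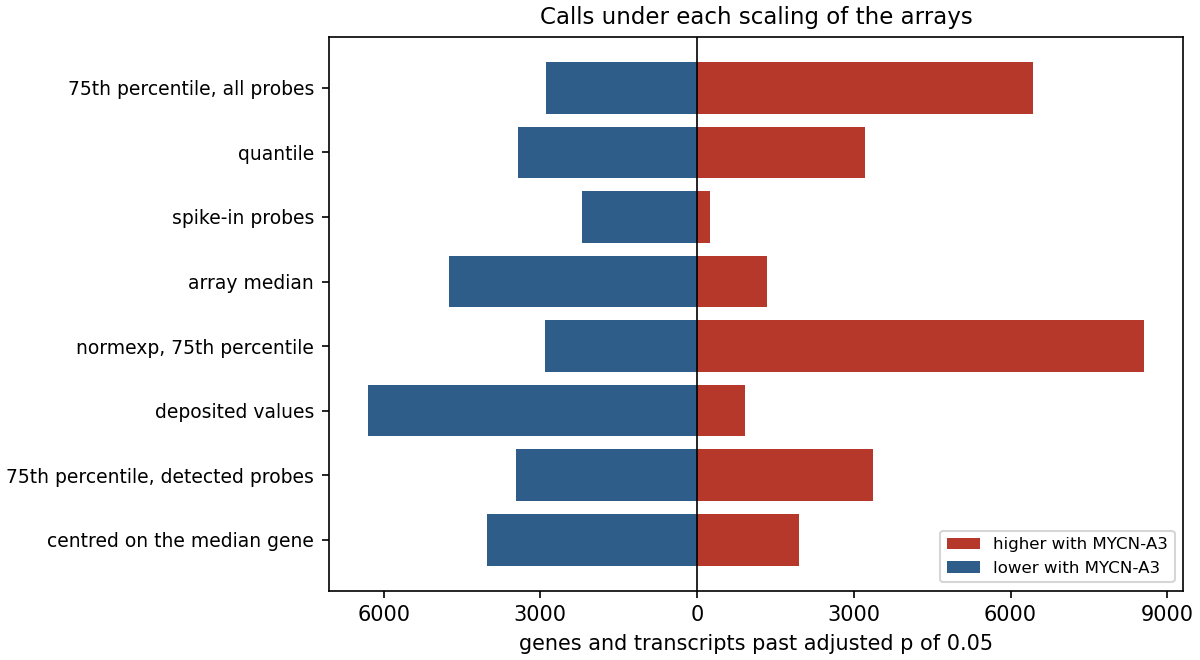
Number of genes and transcripts past an adjusted p of 0.05 (x axis, limma on 2 MYCN-A3 samples and 1 DMSO sample), higher to the right and lower to the left, for each way of scaling the arrays (y axis). Lower calls outnumber higher calls in all scalings but the 75th percentile over all probes, with 6430 higher and 2901 lower, and normexp, with 8559 and 2908.

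Because of that shift, the log2 changes below are relative to the median tested gene unless stated, with the standard error (SE) of the limma fit, and the adjusted p and the fold bounds ("at least") belong to the values scaled to the 75th percentile. A gene is said to rise or fall where it passed that test. For gene lists, a second pair of counts gives the calls with the median gene set to no change.

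MYCN, a single probe with a log2 signal of 15.35 to 15.86 on the 5 arrays, was higher by 0.70 ± 0.22 (SE; adjusted p = 0.045) with the arrays scaled to their 75th percentile, and by 0.22 relative to the median gene. Relative to the median gene it did not pass (adjusted p = 0.40). Not set against the median gene, it was at -0.23 with quantile normalization, -0.38 with spike-in scaling and -0.23 in the deposited values, without passing. Relative to the median gene it was below 0 only with quantile normalization (-0.33), at 0.095 in the deposited values and still at 0.22 with spike-in scaling, which moves all genes alike. Of the 9 measured genes of a list made of MYCN and genes of its chromosome arm, MYCN, DDX1 and ODC1 were higher and CYRIA lower, and 5 did not pass. Adjusted over the list alone, 2 were higher and 1 lower, and relative to the median gene 0 were higher and 3 lower. DDX1, often amplified together with MYCN, changed by 0.44 ± 0.23 and ODC1, the polyamine synthesis enzyme ornithine decarboxylase, by 0.38 ± 0.24. CYRIA was not well above background on any MYCN-A3 array and was at least 1.09-fold lower, a sign that turned with normexp. The values of GREB1, LPIN1, LRATD1, NBAS and TRIB2 were 0.00, -0.96, -1.02, 0.11 and 0.16. Of these, LPIN1 and LRATD1 were lower relative to the median gene (adjusted p = 0.029 and 0.027), and 1 of the 2 LRATD1 probes moved the other way.

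Among genes well above background on all 5 arrays, the 12 with the largest rise were PAQR6, CFP, PSPN, COXFA4L3, GPR199P, CD14, DHX58, BEST2, HEXIM1, SP6, ARC and VMO1, with log2 changes from 4.58 to 3.71, SE of 0.22 to 0.27 and adjusted p of 0.0012 to 0.0013. CFP encodes properdin of the complement system, PSPN the growth factor persephin, CD14 a co-receptor for bacterial lipopolysaccharide, DHX58 the cytosolic RNA sensor LGP2 and ARC a neuronal activity-regulated protein. The 12 with the largest fall were RNA5-8SN5, LIN28B, AEBP2, RAPGEF2, TEX19, NRIP1, EPC2, LRP6, RNF111, MRTFB, VEGFC and TLE4, with log2 changes from -6.09 to -4.75. LIN28B, an RNA-binding repressor of let-7 microRNA maturation, changed by -5.84 ± 0.22 (adjusted p = 0.00098), AEBP2, a subunit of Polycomb repressive complex 2, by -5.76 ± 0.23 (adjusted p = 0.0011), and LRP6, a Wnt co-receptor, by -4.89 ± 0.22 (adjusted p = 0.0012). NRIP1 and TLE4 encode transcriptional co-repressors and VEGFC a lymphangiogenic growth factor. RNA5-8SN5 is 1 of many near-identical copies of the 5.8S ribosomal RNA gene, so which copy was measured is uncertain, and its SE of 0.74 was the largest of the 24. Not set against the median gene, it changed by -4.69 and -6.53 in the 2 treated samples, so the size of its fall is uncertain. Whether the labelling of this ribosomal RNA, with a gene of 0.157 kb, contributed was not tested. All 24 genes moved the same way in both treated samples, which the rule for naming them required. They kept their sign under every scaling, which changes this large would do where all genes of an array shift alike.

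**Figure D2:**
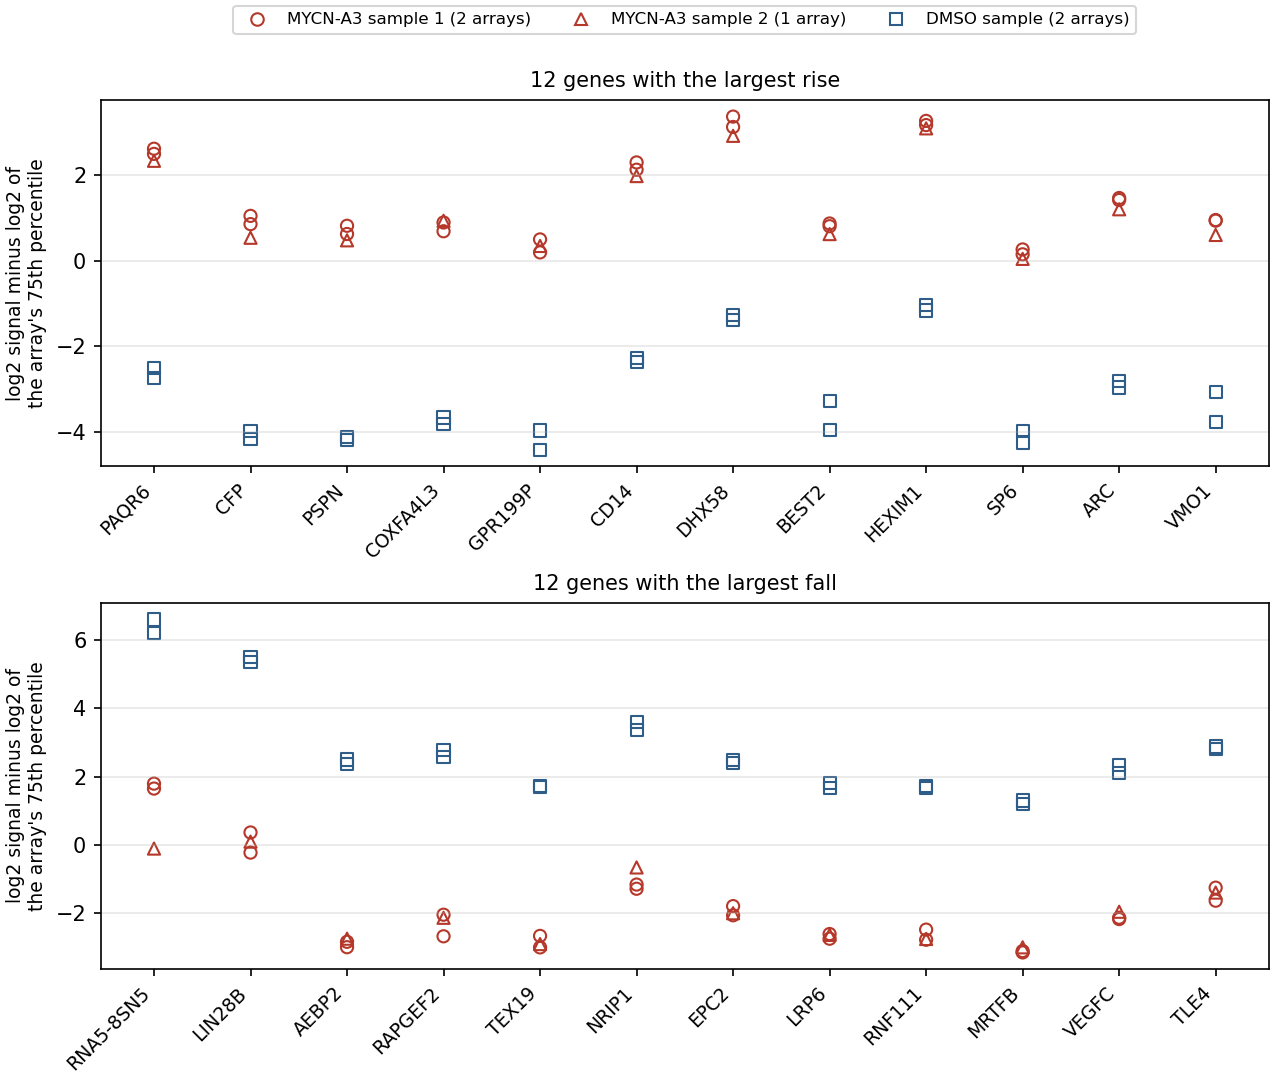
Log2 signal minus the log2 75th percentile of the array (y axis) for the 12 genes with the largest rise (top) and the 12 with the largest fall (bottom). Each point is 1 array, circles for MYCN-A3 sample 1 (2 arrays), triangles for MYCN-A3 sample 2 (1 array) and squares for DMSO (2 arrays), and for each of the 24 genes all MYCN-A3 points lie on 1 side of both DMSO points. The genes were chosen for large changes of the same sign in both treated samples.

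Change depended on gene length, taken as the span in the genome with introns. Across the 13298 tested genes with a symbol, the rank correlation of the log2 change with length was -0.391, -0.397 in MYCN-A3 sample 1 and -0.374 in sample 2. It is a correlation across genes, which are not independent replicates. Between arrays of the same RNA it was -0.057 for DMSO and 0.059 for MYCN-A3 sample 1, and for the difference of the 2 treated samples it was -0.088. Within slide 1 it was -0.378, within slide 2 -0.382, and with slide as a block -0.395. The median gene of the shortest class, up to 5 kb, stood 0.30 above the median of all tested genes, and so did that of the 5 to 10 kb class. The median of the 50 to 100 kb class was -0.58, of the 100 to 200 kb class -0.90, and of the 182 genes over 500 kb -0.998. Of the genes up to 5 kb, 51.3% were called higher and 10.4% lower. Of those over 500 kb, 9.34% were called higher and 39.6% lower. Relative to the median gene, 17.8% of the genes up to 5 kb were called higher and 15.4% lower, and of those over 500 kb 0.55% and 50.5%.

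**Figure D3:**
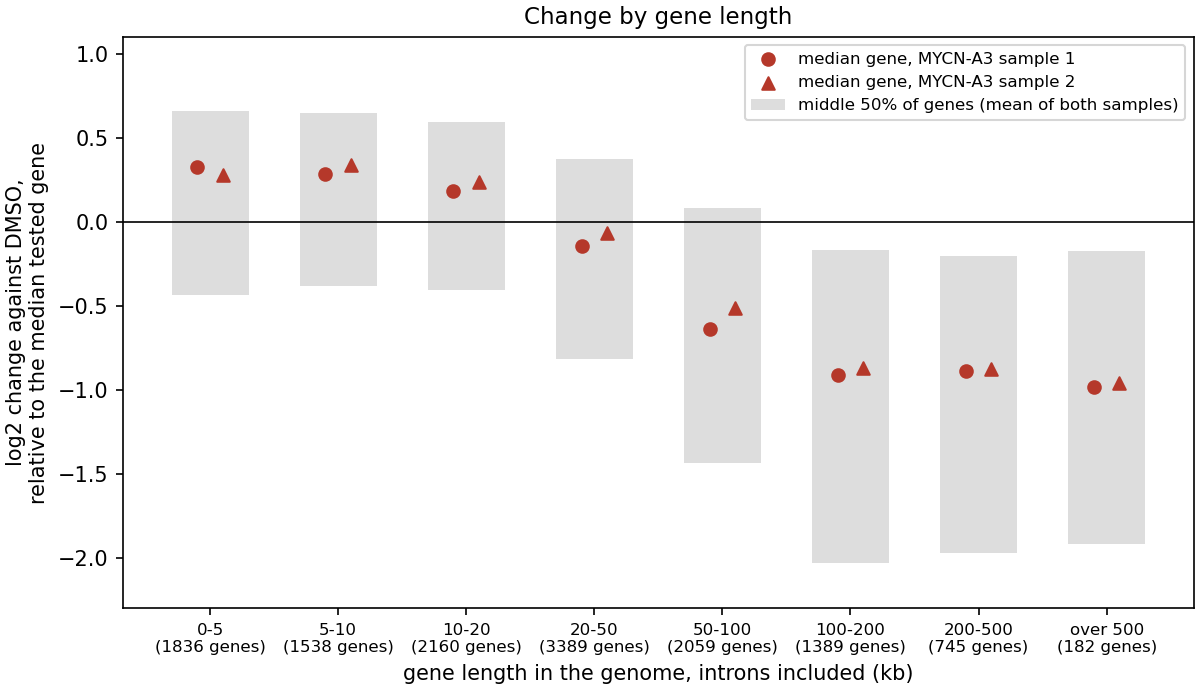
Log2 change against DMSO relative to the median tested gene (y axis) by gene length with introns in kb (x axis). Circles and triangles are the median gene of each class in MYCN-A3 sample 1 and sample 2 and grey bars the middle 50% of genes, and the class medians go from 0.32 and 0.28 up to 5 kb to -0.98 and -0.96 over 500 kb.

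Of the 21 gene lists, 5 stood apart from the other genes (camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 21 lists). Each of the 5 lost its call with the correlation estimated from the residuals, at an adjusted p = 0.964 with an estimated correlation. With 1 residual degree of freedom that test can hardly call any list, and all 21 lists came to an adjusted p of 0.964 or above. The adrenergic list lost its call though its estimated correlation, -0.030, was below the preset 0.01. The test therefore cannot decide whether the lists stand apart, and the calls of the 5 lists rest on the preset correlation. A directional fry test asks another question, whether the genes of a list move on balance one way from no change, and for these lists its adjusted p lay between 0.11 and 0.34.

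Of 48 genes of G2 and mitosis measured, 19 fell, 4 rose and 25 did not pass, and their median was -1.02 (adjusted p = 3.19e-06; adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone, 17 fell and 3 rose, and relative to the median gene 26 fell and 0 rose. AURKA, a spindle pole kinase, changed by -3.14 ± 0.24 (adjusted p = 0.0022), CENPA, the centromeric histone variant, by -2.92 ± 0.22, the spindle checkpoint kinase TTK by -2.70 ± 0.22, and G2E3 by -2.96 ± 0.23. The list median lay between -1.08 and -1.02 under the other scalings. For this and the lists below, only quantile normalization, normexp and the deposited values can move it. The other scalings shift all genes of an array alike.

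Of 50 histone genes measured, with a median length of 0.494 kb, 21 fell, 4 rose and 25 did not pass, with a median of -1.29 (adjusted p = 3.19e-06; adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone the counts were the same, and relative to the median gene 26 fell and 2 rose. The treated samples differed in size, with medians of -0.92 and -1.59. The linker histone genes H1-3, H1-5 and H1-4 changed by -4.65 ± 0.25, -2.51 ± 0.24 and -2.26 ± 0.29, while H1-1, not well above background in DMSO, was at least 2.27-fold higher. Many histone genes are near-identical copies, so values of single members are uncertain. The median lay between -1.29 and -1.09 under the other scalings.

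Of 30 adrenergic identity genes measured, which mark the sympathetic neuroblast state of neuroblastoma cells, 14 fell, 4 rose and 12 did not pass, with a median of -1.003 (adjusted p = 3.28e-04; adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone the counts were the same, and relative to the median gene 18 fell and 0 rose. The lineage transcription factor gene ISL1 changed by -2.77 ± 0.26 (adjusted p = 0.0037). LIN28B, named above, also belongs to the list. LMO3, not well above background on any MYCN-A3 array, was at least 1.73-fold lower. Of the 27 measured mesenchymal and Schwann-like markers, which mark the other described neuroblastoma states, 9 were higher and 5 lower (adjusted p = 0.73; adjusted over the list alone 10 and 5; relative to the median gene 4 and 7). PDGFRA changed by -3.31 ± 0.30, PRRX1 was at least 5.72-fold lower, and ERBB3 and TAGLN were at least 3.42-fold and 2.69-fold higher.

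Of 76 cytosolic ribosomal protein genes 74 were higher and 0 lower, with a median of 0.49 (adjusted p = 1.61e-06; adjusted p = 0.964 with an estimated correlation). Of 54 genes of oxidative phosphorylation 42 were higher and 0 lower, with a median of 0.50 (adjusted p = 5.95e-05; adjusted p = 0.964 with an estimated correlation). Adjusted over the list alone, 75 and 44 were higher. Relative to the median gene only 1 ribosomal protein gene was higher and 0 were lower, and 3 genes of oxidative phosphorylation were higher and 1 lower. Quantile normalization ended both calls (adjusted p = 0.74 and 0.44) and took the medians to -0.06, which turns the sign for the ribosomal proteins, and 0.04. Among the ribosomal proteins, RPL27A changed by 1.01 ± 0.22 and RPS15 by 1.02 ± 0.40, and 2 of the 3 RPL28 probes moved opposite to the one used. NDUFB7, NDUFS8, NDUFA1 and NDUFB10, subunits of respiratory complex I, changed by 0.82, 0.80, 0.79 and 0.91. Ribosomal protein genes have many processed pseudogenes, so their probes may not be specific.

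**Figure D4:**
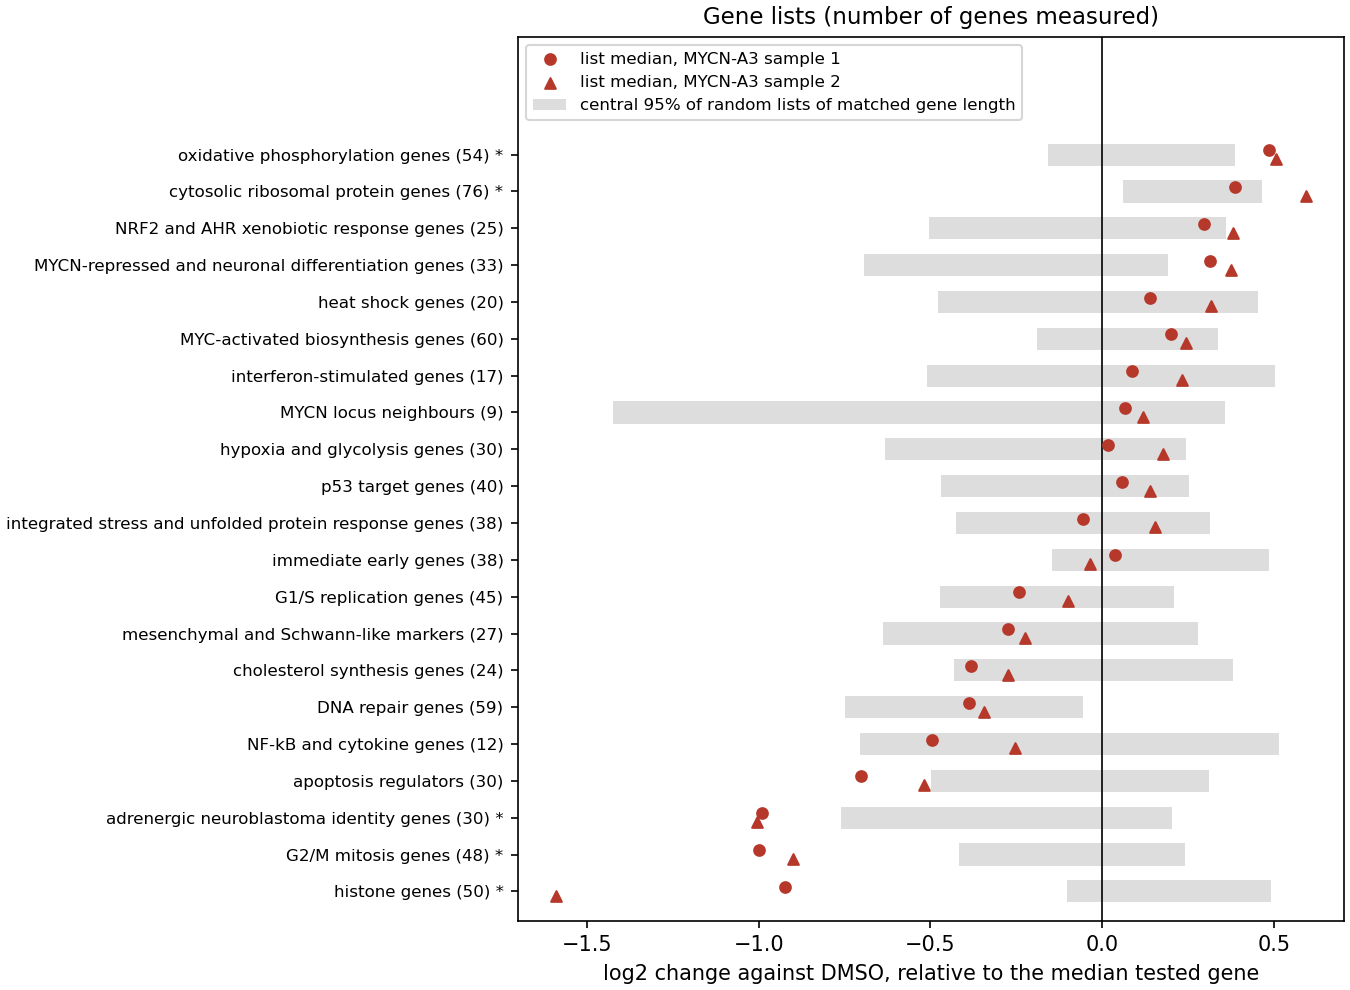
Median log2 change against DMSO relative to the median tested gene (x axis) of 21 gene lists (y axis, with the number of genes measured), circles for MYCN-A3 sample 1 and triangles for sample 2. Grey bars span the central 95% of 10000 random lists of matched gene length (from the mean of both samples), stars mark the 5 lists past an adjusted p of 0.05 with a preset correlation, and the histone list lies lowest, at -0.92 and -1.59.

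Targets of p53 moved in both directions. Of 40 measured, 16 rose, 7 fell and 17 did not pass, and as a list they did not stand apart (adjusted p = 0.73). The counts were the same adjusted over the list alone, and relative to the median gene 11 rose and 8 fell. GDF15, a secreted stress cytokine, changed by 3.49 ± 0.22 (adjusted p = 0.0012), the kinase gene PLK2 by 3.38 ± 0.32 (adjusted p = 0.0020) and BBC3, which encodes the pro-apoptotic protein PUMA, by 2.89 ± 0.23 (adjusted p = 0.0014). KITLG fell, but it was well above background on only 2 of the 3 MYCN-A3 arrays, so no size is given. Chosen after their values were seen, CDKN1A, the p21 cell cycle inhibitor, changed by 1.73 ± 0.23 and MDM2, the ubiquitin ligase of p53, by -1.53 ± 0.23, with 1 of its 4 probes moving the other way. Of 30 apoptosis regulators 11 were higher and 7 lower (adjusted p = 0.33; adjusted over the list alone 11 and 8; relative to the median gene 2 and 11). PMAIP1, which encodes the pro-apoptotic protein NOXA, changed by 1.44 ± 0.24, and FADD, the death receptor adaptor, by -2.22 ± 0.22. BCL2 was at least 1.88-fold lower, a sign that turned with normexp.

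Of 59 DNA repair genes 9 were higher and 15 lower (adjusted p = 0.096; adjusted p = 0.964 with an estimated correlation; adjusted over the list alone 5 and 11; relative to the median gene 1 and 20). REV3L, the catalytic subunit of translesion polymerase zeta, changed by -4.28 ± 0.24 (adjusted p = 0.0013), FANCM, a Fanconi anaemia DNA translocase, by -3.57 ± 0.22 and the helicase BLM by -3.14 ± 0.22. ERCC6, of transcription-coupled repair, was at least 5.43-fold lower. The list passed in the same direction with normexp (adjusted p = 0.0021), the deposited values (0.0073) and the median gene set to no change (0.029). Its median of -0.35 lay at percentile 52.3 of random lists of matched gene length, whose median was -0.36. Of 45 genes of G1/S and replication 14 were higher and 6 lower (adjusted p = 0.71; adjusted over the list alone 8 and 4; relative to the median gene 1 and 13). POLD3, a subunit of DNA polymerase delta, changed by -4.61 ± 0.25, EXO1 by -2.28 ± 0.29, DTL by -1.64 ± 0.22 and MCM5 by 0.81 ± 0.22.

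Of 60 biosynthesis genes that MYC proteins activate, 30 were higher and 6 lower (adjusted p = 0.61; adjusted over the list alone 30 and 7; relative to the median gene 5 and 12). The 4 members with the largest change fell. RCL1 changed by -3.82 ± 0.22, WDR43 by -3.53 ± 0.24, PPAN by -2.18 ± 0.32 and POLR1B, a subunit of RNA polymerase I, by -2.11 ± 0.25, and the first 3 take part in ribosome biogenesis. The list median was 0.24 and lay between -0.12 and 0.24 under the other scalings. Of 33 genes that MYCN represses or that mark neuronal differentiation, 20 were higher and 4 lower (adjusted p = 0.21; the same counts adjusted over the list alone; relative to the median gene 10 and 4). CHGB, a secretory granule protein, changed by 1.34 ± 0.22 and SYN1, a synaptic vesicle protein, by 1.25 ± 0.22. The Wnt inhibitor gene DKK1 and the phosphatase gene PTPRD fell, but they were well above background on only 1 and 2 of the 3 MYCN-A3 arrays, so no size is given.

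Of 38 immediate early genes 13 were higher and 8 lower (adjusted p = 0.87; the same counts adjusted over the list alone; relative to the median gene 10 and 14). ARC is named above, ZFP36, which encodes an mRNA decay factor, changed by 2.79 ± 0.23, FOSB was at least 7.43-fold higher, and TIPARP changed by -3.96 ± 0.23. Of 38 genes of the integrated stress and unfolded protein responses 17 were higher and 6 lower (adjusted p = 1.00; the same counts adjusted over the list alone; relative to the median gene 3 and 10). The stress transcription factor ATF3 changed by 2.38 ± 0.24, DNAJB9 by -2.66 ± 0.25 and SEL1L, of endoplasmic reticulum-associated degradation, by -2.27 ± 0.26, while VLDLR was at least 3.37-fold lower. Of 20 heat shock genes 10 were higher and 1 lower (adjusted p = 0.33; the same counts adjusted over the list alone; relative to the median gene 0 and 2). HSPA1B changed by 0.92 ± 0.29, and STIP1, HSPB1 and HSP90AB1 by 0.59, 0.55 and 0.52.

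Of 17 interferon-stimulated genes 8 were higher and 0 lower (adjusted p = 0.48; adjusted over the list alone 7 and 0; relative to the median gene 3 and 2). IRF1 was at least 4.03-fold higher, ISG20 changed by 2.24 ± 0.22, IFI35 by 0.99 ± 0.25 and IFI6 by 0.44 ± 0.22. Of 12 NF-kB and cytokine genes 4 were higher and 4 lower (adjusted p = 0.55; the same counts adjusted over the list alone; relative to the median gene 2 and 4). NFKBIE and NFKB1 changed by -2.67 ± 0.25 and -2.32 ± 0.26 and BCL3 by 0.95 ± 0.23. Of 25 genes of the NRF2 and AHR responses to oxidants and xenobiotics 13 were higher and 2 lower (adjusted p = 0.48; adjusted over the list alone 14 and 2; relative to the median gene 1 and 3). GCLC, of glutathione synthesis, changed by -2.43 ± 0.22 and CYP1A2 by 0.79 ± 0.25.

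Of 24 cholesterol synthesis genes 6 were higher and 6 lower (adjusted p = 0.33; adjusted over the list alone 5 and 6; relative to the median gene 1 and 8). MVK, mevalonate kinase, changed by -2.08 ± 0.22 and MVD by 1.01 ± 0.22. Of 30 hypoxia and glycolysis genes 11 were higher and 5 lower (adjusted p = 1.00; adjusted over the list alone 14 and 5; relative to the median gene 3 and 7). ADM changed by 1.75 ± 0.22 and ANKRD37 by -2.07 ± 0.22. EGLN3 and KDM3A were at least 6.27-fold and 1.84-fold lower, the latter with the opposite sign under normexp. For the MYCN locus and the hypoxia list the median lay above that of all genes while the mean and the camera direction lay below, and the stress response list differed likewise. For the immediate early genes the median and the camera direction lay below and the mean above.

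Detection itself changed. Of the tested genes and transcripts, 313 were well above background on all MYCN-A3 arrays and on neither DMSO array, and 865 were well above background on both DMSO arrays and on no MYCN-A3 array. Of these, 154 and 607 had a symbol. The bound was at least 10-fold for only 40 of the 313 and 28 of the 865, and for the others it was smaller or absent. The treated arrays were dimmer, and whether this took dim genes below the call was not tested. The following were chosen after their values were seen, by the size of the bound. SBSN was at least 158.5-fold higher, GRIN2C, an NMDA receptor subunit, at least 76.6-fold, SFN, the 14-3-3 sigma protein, at least 70.9-fold, and LEFTY1, a secreted Nodal inhibitor, at least 68.3-fold. KCTD8 was at least 35.5-fold lower, PLPP3 at least 32.8-fold, the glucocorticoid receptor gene NR3C1 at least 26.2-fold, and the mitotic kinesin gene KIF18A at least 20.3-fold. No gene over 500 kb was newly detected and 17.6% of them were no longer detected, against 2.89% and 2.56% of the genes up to 5 kb.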

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

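Limits first. Only 3 RNA samples were measured, the single DMSO sample has no spread of its own, and genes not well above background in a group have only a bound. No paired analysis was possible because the shared numbers in the titles name technical arrays of 1 RNA, and the groups share only RNA sample number 1. Chosen after seeing the data were the 75th percentile over detected probes, centring on the median gene, the single slides and the length relation over subsets of genes. A spliced transcript length, planned for the length relation, was not run, because the gene table used gives none. Where no cause is named below, the cause was not tested.

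The count of 9331 calls became 2443 with spike-in scaling (240 higher), 6103 with the array median, 5177 without a filter on dim probes and 5963 centred on the median gene. With the other alternatives it lay between 6637 and 12587, the highest with the 5 arrays taken as independent, which counts arrays of 1 RNA as replicates. The count of 5297 genes changed at least 2-fold became 2661 with normexp and 9013 without a filter, where more genes were tested.

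Where the MYCN change of 0.70 turned its sign, it was not past the threshold. It was at -0.23 (SE 0.19) with quantile normalization, -0.38 (SE 0.81) with spike-in scaling and -0.23 (SE 0.27) with the deposited values. It was no longer past the threshold at 0.066 with the array median, 0.42 with the 75th percentile over detected probes, 0.23 centred on the median gene, 0.67 on slide 1 alone, where fewer arrays were used, and 0.70 without a filter on dim probes, where the SE rose to 0.55. Leaving out single arrays gave 0.67 to 0.73, with adjusted p of 0.048 to 0.064, and leaving out a treated sample 0.65 and 0.74. On slide 2 alone, with no test, it was 0.67, and with slide as a block 0.67 (adjusted p = 0.0048, over 5 arrays of only 3 RNA samples, so arrays of 1 RNA count as replicates).

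The rank correlation with gene length stayed negative under every alternative. Scalings that shift all genes of an array alike cannot change it. Beyond the spread between the treated samples it moved to -0.352 with quantile normalization, -0.313 without a filter, -0.369 with probes well above background on all arrays, -0.369 over genes measured on both sides, -0.408 over protein-coding genes, and, leaving out a treated sample, lay between -0.398 and -0.370.

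The values in this paragraph are not set against the median gene, and spike-in and array median scaling move all genes alike, so there a turned sign reflects that shift. Of the other named genes, DDX1 turned to -0.078 with quantile normalization, -0.16 with spike-in scaling and -0.020 with the deposited values, and ODC1 to -0.053, -0.22 and -0.038. With spike-in scaling GREB1 was at -0.60, NBAS -0.49, TRIB2 -0.44, STIP1 -0.013, HSPB1 -0.054, HSP90AB1 -0.078 and IFI6 -0.16. With the array median GREB1 was at -0.15 and NBAS at -0.049, and with the deposited values GREB1, NBAS and TRIB2 were at -0.40, -0.28 and -0.29. With normexp CYRIA, BCL2 and KDM3A turned to 0.20, 0.048 and 0.012, and with the mean over probes RPL28 turned to -0.30.

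Of the list tests, the 5 calls were lost with an estimated correlation (adjusted p = 0.964). With 1 residual degree of freedom that test can hardly call any list. Fry tests lists against no change, not against other genes: none passed the directional test, and 11 lists without a camera call passed the mixed test, for change in either direction. The ribosomal protein and oxidative phosphorylation lists also lost theirs with quantile normalization and without a filter (adjusted p = 0.050 and 0.19). The DNA repair list passed the camera test, lower, in 6 alternatives, among them no filter and the filter on all arrays. Cholesterol synthesis genes passed, lower, with normexp (adjusted p = 0.015) and without a filter (0.0041), G1/S genes, lower, without a filter (0.0071), and neuronal differentiation genes, higher, with the filter on all arrays (0.021). These calls and those of the DNA repair list used the preset correlation. With an estimated correlation none of these lists passed with the main settings. No list call reversed.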

Other observations

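Of the tests below, those on dimmer signal, on slide or array differences and on gene length within lists were chosen after the result was seen, and those on stray probes and neighbour genes after the newly detected genes were seen but before their own values were.

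The median changes of transcripts without a gene symbol lay above that of named protein-coding genes. Of 745 tested transcripts of the array's lincRNA catalogue, 411 were higher and 41 lower, with a median of 0.39 relative to all tested features, and of 1354 Ensembl transcripts without a symbol 629 were higher and 131 lower, with a median of 0.25. Of 1717 other transcripts without a symbol 932 were higher and 112 lower, with a median of 0.38. Of 12235 named protein-coding genes 4022 were higher and 2524 lower, with a median of -0.16. Relative to the median gene, 19.6% of the lincRNA catalogue transcripts, 18.5% of the Ensembl transcripts and 16.0% of the others were higher and 8.73%, 13.9% and 9.90% lower, against 9.0% and 28.2% of the protein-coding genes. In the same order, 5.77%, 3.84% and 3.73% were newly detected, against 1.07% of the protein-coding genes. No longer detected were 6.17%, 8.20% and 5.88%, against 4.55%. Whether signal near the detection limit contributed to the higher medians was not tested. MYC, the paralog of MYCN and chosen after its value was seen, changed by 1.35 relative to the median gene (adjusted p = 0.010). Against random lists of matched gene length, neuronal differentiation genes lay at percentile 99.83, NRF2 and AHR genes at 97.93 and apoptosis regulators at 0.69. None of them passed camera as a list (adjusted p = 0.21, 0.48 and 0.33). An exception was the neuronal differentiation list with the filter on all arrays (camera, adjusted p = 0.021). That call used the preset correlation, and with an estimated one the list did not pass with the main settings. The log2 75th percentile of the signal fell by 1.01 from the DMSO sample to the mean of the treated samples. The spike-in mean did not follow one direction, at 11.19 and 11.46 on the arrays of MYCN-A3 sample 1 and 10.50 on that of sample 2, against 11.04 and 10.65 on the DMSO arrays. The log2 75th percentile minus the spike-in mean was lower on every treated array. It was -3.84 and -3.79 for MYCN-A3 sample 1 and -2.97 for sample 2, against -2.48 and -2.15 on the DMSO arrays.

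Long genes fell relative to short genes. Reduced transcription through long genes could give this and stays open, since no value here other than the pattern itself bears on it. Dimmer signal of long genes is argued against, since given the DMSO signal the correlation was -0.3909. Slide or array differences are argued against, since on slide 2 alone it was -0.382 and between arrays of 1 RNA within 0.059 of 0. Degradation of long mature transcripts was not tested, so the pattern is not called biological here.

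Gene length alone is argued against for 4 of the 5 shifted lists. Against the median of random lists of matched length, histone genes lay at -1.516 log2 units, mitosis genes at -0.969, adrenergic identity genes at -0.780 and oxidative phosphorylation genes at 0.324, and in both treated samples these list medians lay outside the central 95% of random lists. For ribosomal protein genes, at 0.198, MYCN-A3 sample 1 lay inside that range and sample 2 outside, so length alone cannot be told apart from a further shift. For oxidative phosphorylation and ribosomal protein genes a difference of signal distributions between the arrays also stays open, since quantile normalization ended both calls (adjusted p = 0.44 and 0.74). Random lists were not drawn with quantile normalization, under which the oxidative phosphorylation median was 0.04, so there length alone was not tested. A shorter mRNA half-life of the genes that fell, and the priming used for labelling, which matters for histone mRNAs without a poly(A) tail, may contribute and were not tested.

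The 154 named genes detected only after treatment had a median length of 9.09 kb, against 16.9 kb for never-detected genes. The median was 27.3 kb for all tested genes and 78.8 kb for genes no longer detected. Whether raised background on the treated arrays contributed was not tested and stays open. Whether single stray probes are the whole source cannot be decided here. In 48% of the 25 such genes with several probes another probe was at least 2-fold higher in both treated samples, against 13.5% of never-detected genes. These values are scaled to the 75th percentile, whose log2 changed by -1.01 with treatment, so a probe of unchanged signal would read close to this cutoff. The never-detected genes carry the same shift, but all their probes were dim on every array. Transcription from expressed neighbour genes is a candidate explanation, since an adjacent gene was expressed in DMSO for 91.6% of them, 28.4 percentage points more than for never-detected genes of matched length (95% interval 23.6 to 32.7; permutation p = 1e-04, the smallest that 9999 permutations can give). Genes detected in DMSO of the same length had such a neighbour in 91.2%, so induction of genes that lie among expressed genes would give the same share, and both stay open.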
